A study of Mus musculus with 2 samples.

How the data were processed

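Bone marrow cells were cultured for 5 days with 10% serum and 10% supernatant of L929 cells, a mouse fibroblast line that secretes macrophage colony-stimulating factor, per the labels' protocols. RNA was enriched for polyadenylated molecules before library preparation, and the libraries were circular single-stranded DNA. The deposited data were 1 table of 16463 genes with counts and FPKM for each library, and 0 columns of per-sample values went unmatched. The table names the columns by genotype at 0 h, and they were assigned to the 1 unstimulated sample of each genotype.

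Per the submitters' processing notes, which give no roles, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 were used with the mm10 build; the annotation and filters are not given in the sources used here. The deposited expected counts are estimated reads per gene, of which 21.3% in WT and 21.1% in TKO were not whole. The deposited FPKM values, so named per the file headers, are in a unit scaled for gene length and depth, and all 875 WT and 860 TKO genes at 0 counts are listed at 0.01. The authors' log2 ratio equals the log2 of TKO FPKM over WT FPKM. The authors' p-value comes from a test that is not given in the sources used here. The authors' FDR is treated as a score because 713 values exceed 1. The deposited table also gives a length in bases per gene.

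Expected counts were rounded to whole numbers and scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.01 for WT and 0.988 for TKO). The log2 ratio had no pseudocount, and a count of 0 was replaced by 3, the number of counts that an observed 0 allows. This makes the ratio a bound for the 0 only, without the counting error of the other library. Its 95% interval was the exact conditional binomial (Clopper-Pearson) interval. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per genotype, no test was run and no p-value was computed. A gene was called higher or lower by a size rule: an absolute log2 ratio of at least 1, an interval that excluded 0 and at least 20 counts in 1 library.

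For 31 gene lists the median log2 ratio of members past the count minimum was given with a binomial order-statistic interval over members. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test. A second set of random lists was matched on expression in 10 bins and gene length in 8 bins. For 4 microRNA seed families, the 7mer-m8 site was searched for in the longest annotated 3' UTR of each gene; 474 genes past the count minimum had no 3' UTR to search and counted as not searched. Random lists were matched on expression, and as an alternative on 3' UTR length in 10 bins. The median of each site was ranked among heptamers found in at least 100 genes. Gene Ontology terms of 10 to 300 measured genes were treated like the lists.

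Coordinates, names and 3' UTRs came from GENCODE M21 on GRCm38, the assembly behind mm10; 16279 of the 16463 genes matched, 15321 by Entrez identifier. The size rule, lists, sites and the rule for naming genes were fixed before the data were examined. Named were Mir17hg, Mcm7, Kis2 (not analysed here) and Lyz2; the 12 highest and 12 lowest genes past the size rule with an FPKM of at least 5 in 1 library, ranked by the interval bound nearest to no change and leaving out predicted and unnamed genes; and in each list up to 4 members with the largest absolute ratio, the most abundant member and any published target. Some genes that this rule takes are not reported here.

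The size rule was tested on simulated data for TKO against WT, with 200 of 16463 genes changed. With counting error alone it called 51 of 100 genes changed by a log2 ratio of 1, where the threshold itself lies, 100 of 100 changed by 2 and 24 of 11264 unchanged genes. Adding a 10% spread between cultures raised the last to 59 of 11282 and lowered the share of 95% intervals that held the true ratio from 95.3% to 64.7%. Of 1000 random lists of 25 genes, 4.2% lay outside the central 95% of their percentiles with counting error alone, and 5.0% with the added spread. Random lists were compared there with random lists of the same simulated values, so a share near this size was built in. The simulated genes had no trend with length and were independent, so the share does not calibrate the percentiles of the real lists.

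Alternatives were scaling by library totals, size factors from DESeq2 1.42.0, log2 of FPKM plus 1, count minimums of none and 100, thresholds of 1.5-fold and 4-fold, a wider counting interval, other matchings of random lists and other definitions of seed sites. The setting with no count minimum kept only genes above 0 counts in both libraries. Chosen after seeing the data were removal of the lowess trend (span 0.3) of the ratio with gene length or 3' UTR length, leaving out the MHC region, the ranks of sites after the 3' UTR trend was removed, sums of counts over related genes, the description of the ratio by gene length, the shares of genes by window of the genome and the count of genes near absent from 1 library. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.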

Results

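Messenger RNA was profiled in unstimulated bone marrow-derived macrophages of mice labelled C57BL/6J, which are macrophages grown in culture from marrow precursors. The 2 libraries came from a control mouse line carrying Lyz2-Cre, a recombinase expressed from the lysozyme M locus in myeloid cells (WT), and from a line labelled as lacking the mir-106a~363 and mir-106b~25 clusters and with a floxed mir-17~92 cluster plus Lyz2-Cre (TKO). The 3 clusters are paralogs that encode the miR-17, miR-18, miR-19 and miR-25/92 seed families. Each genotype had 1 library, with 10877917 estimated counts in WT and 10656465 in TKO. The comparison asks how the transcriptome of resting macrophages differed between the labelled genotypes. No difference below has a replicate check, and all intervals for single genes cover counting error only.

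The host transcripts of the targeted clusters were examined first. Mir17hg (Entrez 75957, chromosome 14, 115042879 to 115046727, GRCm38), the noncoding host gene of mir-17~92, had 8 counts in WT and 42 in TKO, which is 5.49-fold higher in TKO (95% interval 2.55 to 13.5). Mcm7 (Entrez 17220, chromosome 5, 138164583 to 138172422), a DNA replication helicase gene with mir-106b~25 in an intron, had 1228 and 1083 counts, a log2 ratio of -0.12 (-0.23 to 0.00). Lyz2 (Entrez 17105, chromosome 10, 117277331 to 117282321), the lysozyme gene into which Cre is placed, had 373 and 397 counts, a log2 ratio of 0.16 (-0.05 to 0.36). These values are for whole host genes, and mature microRNAs were not measured in polyadenylated RNA, so they do not check the deletions or the genotype labels.

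Most transcripts were at similar levels in both libraries, while MHC class I genes and interferon-stimulated genes were higher in TKO and collagen and other matrix genes were lower. Of 11525 genes with at least 20 counts in 1 library, 280 were higher and 265 lower in TKO by 2-fold or more with an interval that excluded no change. Among these, 76 were higher and 26 lower by 4-fold or more. The log2 ratio was within 0.5 of 0 for 83.7% of the genes. With log2 of FPKM plus 1 in place of counts, 213 genes were higher and 122 lower. That setting is a different rule, as it took genes with an FPKM of at least 1 in 1 library and used no counting interval. The added 1 also shrinks the ratios of low values. In the authors' deposited table, 300 genes were higher and 324 lower at an FDR of 0.05 and an absolute log2 ratio of 1, a threshold chosen here after the table was seen because it marks none.

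**Figure D1:**
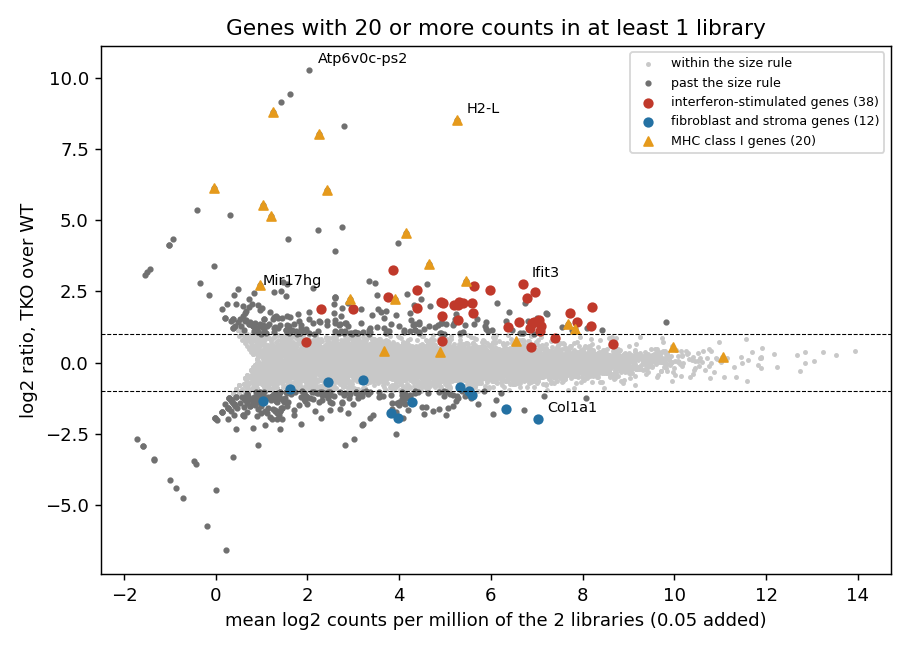
Log2 ratio of TKO over WT (y axis) against mean log2 CPM of the 2 libraries (x axis) for 11525 genes, each point 1 gene, with dashed lines at log2 ratios of -1 and 1 and a count of 0 replaced by 3. The 38 interferon-stimulated genes lie above 0, the 12 fibroblast and stroma genes lie below 0, and H2-L is at 8.50, among the highest points.

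Interferon-stimulated genes, the antiviral and antimicrobial genes switched on by interferon signalling, were higher in TKO as a group. All 38 listed genes had a log2 ratio above 0, and 33 of them were higher by the size rule. The median log2 ratio was 1.81 (95% interval over members 1.42 to 2.09), a 3.50-fold difference. Ifit3 (Entrez 15959, chromosome 19, 34583531 to 34588731), which forms complexes with other Ifit proteins, had 440 counts in WT and 2844 in TKO, or 6.76-fold more (6.12 to 7.50). Its close paralog Ifit3b was 9.52-fold higher, and the division of reads between the pair is uncertain. Zbp1, a sensor of Z-form nucleic acid, was 6.42-fold higher and Ifit1 5.79-fold higher. Parp14, the most abundant member, had a log2 ratio of 0.66 and did not pass the size rule. The group's median stood at percentile 100 of 10000 random lists matched on expression, and at percentile 100 when gene length was matched too.

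Inflammatory genes were higher in TKO as well, by a smaller median. Of 22 measured cytokine and activation genes, 6 were higher, none was lower by the size rule and 19 lay above 0, with a median log2 ratio of 0.56 (0.11 to 1.08). The chemokine genes Ccl4 and Ccl5 were 2.84-fold and 2.62-fold higher and Acod1, the enzyme that makes itaconate, 2.56-fold higher. Il1b, an inflammatory cytokine, was 2.34-fold higher on few counts, 21 and 47 (1.37 to 4.12). Icam1, the most abundant member, had a log2 ratio of 0.57 (0.43 to 0.71). The median was at percentile 100 of both kinds of random lists.

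Several MHC genes were near absent from the WT library and abundant in the TKO library. H2-L (Entrez 14980), a class I gene, had 22 counts in WT and 7629 in TKO, a 363-fold difference (240 to 579). H2-Q10 (chromosome 17, 35470089 to 35474563) had 1 and 422 counts, a log2 ratio of 8.79 (6.30 to 14.09), and H2-Q2 had 3 and 741, a log2 ratio of 8.01 (6.46 to 10.30). H2-Q6, with 0 and 200 counts, was at least 69.8-fold higher, and H2-Ea-ps, a class II pseudogene with 0 and 118 counts, at least 41.2-fold higher when the 0 was set to 3 counts. H2-T9, H2-Q8, H2-Q1 and H2-M2 were 66.2-fold, 23.6-fold, 46.7-fold and 35.3-fold higher. Class I genes share long stretches of sequence, so the division of reads among them is uncertain. Summed over 20 class I genes, a sum added after the values were seen, the counts were 35750 in WT and 58929 in TKO, 1.72-fold higher (log2 ratio 0.79, 0.77 to 0.81). The classical genes H2-K1 and H2-D1, added likewise, together had 31002 and 36753 counts, 1.24-fold higher.

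**Figure D2:**
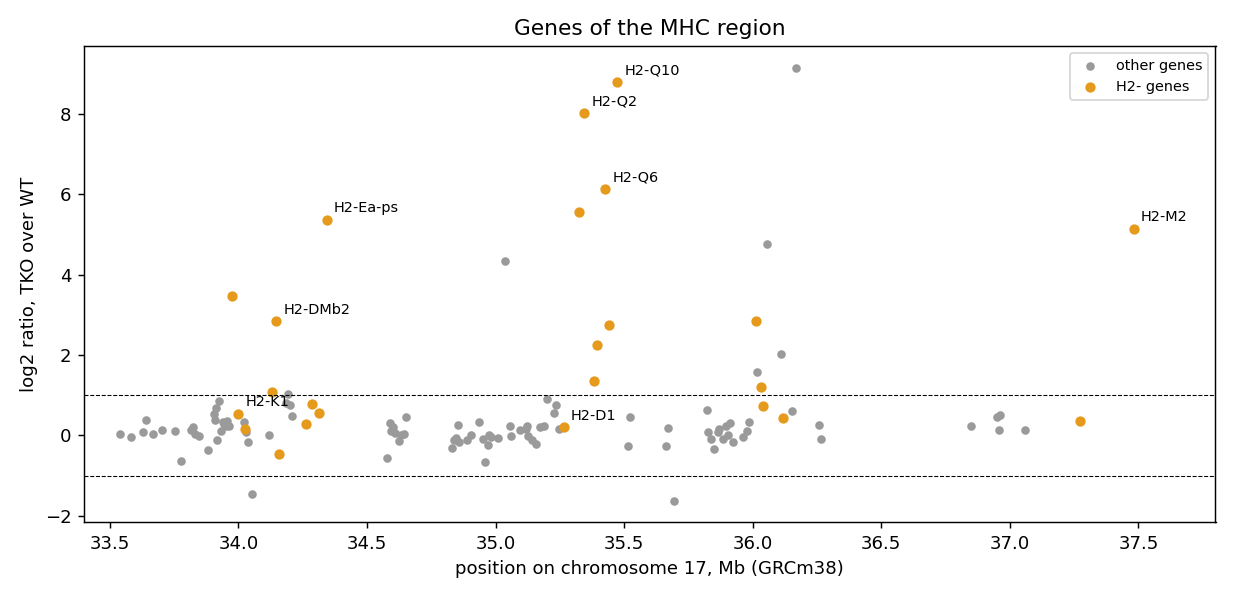
Log2 ratio of TKO over WT (y axis) against gene position (x axis, Mb on chromosome 17, GRCm38) for 126 genes in a window of 4.5 Mb that ends at 38 Mb, each point 1 gene, with the 24 H2- genes in orange and dashed lines at log2 ratios of -1 and 1. H2-Q10 at 8.79 and H2-Q2 at 8.01 stand far above most neighbouring genes, and 1 predicted gene without an H2- name lies higher still.

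MHC class II presentation genes had 2 of 8 measured members higher by the size rule and a median log2 ratio of 0.61 (-0.47 to 2.83). H2-DMb2 was 7.14-fold and H2-DMa 2.13-fold higher, and both encode parts of the peptide-exchange molecule of this pathway. With the length trend removed H2-DMa had a log2 ratio of 0.97. H2-Aa and Cd74, the invariant chain, had log2 ratios of 0.78 and 0.66. The median was at percentile 100 of expression-matched lists and 99.97 with length matched too, and 7 of the 8 members lay above 0.

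A gene copy was also among the highest ratios. Atp6v0c-ps2, a processed pseudogene of a proton pump subunit (chromosome 6, 37806086 to 37806550), had 0 and 3542 counts, and with the 0 set to 3 counts it was at least 1236-fold higher. Reads of such a copy can be assigned to the parent gene or to the copy. Summed with the parent gene the difference was smaller, as Atp6v0c plus Atp6v0c-ps2 had 5957 and 8078 counts (log2 ratio 0.50). The parent was added after its values were seen. Atp6v0e2, another proton pump subunit gene, had 10 and 239 counts, 25.0-fold more in TKO (13.4 to 52.8).

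Genes of the extracellular matrix made up most of the genes named as lowest in TKO. Col1a1 (Entrez 12842, chromosome 11, 94936224 to 94953042), which encodes a chain of type I collagen, had 2871 counts in WT and 693 in TKO, 3.96-fold lower (3.64 to 4.31). Col3a1 was 3.88-fold lower, Postn, a matrix protein of connective tissue, 3.86-fold, Col5a1 3.52-fold, Col6a2 3.33-fold, Timp3, a metalloproteinase inhibitor, 3.27-fold, Fn1, fibronectin, 3.18-fold and Col1a2 3.11-fold lower. Among the fixed markers of fibroblasts and stroma, all 12 measured members lay below 0 and 7 were lower by the size rule, with a median log2 ratio of -1.25 (-1.78 to -0.85), at percentile 0 of the random lists under both matchings. Fbn1 had a log2 ratio of -1.78. Outside the matrix, Cbl, a ubiquitin ligase that acts on receptors, was 3.50-fold lower (3.11 to 3.93), the histone gene Hist1h2ao 3.58-fold and Wdfy1 3.06-fold lower. Hist1h2ao belongs to a family of near-identical histone genes, so its counts are uncertain. Mir8114, which overlaps Glul and Teddm2 in the annotation, had 33 and 0 counts, at least 10.5-fold lower, and its counts are uncertain as well.

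Markers of other cell types were compared because they can differ with the makeup of a culture. Dendritic cell markers were higher, with 4 of 6 measured members past the size rule and a median log2 ratio of 1.33 (-0.02 to 1.53). Itgax, the integrin CD11c, was 2.58-fold higher, Cd24a 2.45-fold, Flt3, a cytokine receptor, 2.83-fold and Dpp4 2.88-fold higher, while Irf8, the most abundant, had a log2 ratio of -0.023. Monocyte markers went both ways, with a median of -0.071 over 8 genes, of which 2 were higher and 0 lower by the size rule. The interval over members, -0.65 to 3.18, spans all 8 genes, so the largest rise was far above the median. The median was 0.14 with FPKM, and 0.49 with no count minimum among genes above 0 counts in both libraries. Plac8 was 2.86-fold higher, whereas F13a1 had a log2 ratio of -0.65. Neutrophil markers had a median of -0.078 over 5 genes (0.023 with FPKM and 0.65 with no count minimum, again above 0 in both). Among them Mmp9 was 2.62-fold lower and S100a8 2.44-fold higher (log2 ratio 1.29, or 0.98 with the length trend removed). The 6 measured osteoclast markers had a median of -0.37 (-0.19 with the length trend removed), and none passed the size rule. In the lists for B cells, T and NK cells and megakaryocytes 2 markers each reached the count minimum. Ebf1, a B cell transcription factor, was 2.51-fold lower and Cd79b had a log2 ratio of -0.37 with an interval that includes 0. Cd4 was 2.45-fold lower, while Il7r, the more abundant marker of T and NK cells with 2102 and 2145 counts, had 0.095. Vwf and Pf4 had log2 ratios of 0.58 and -0.20. No mast cell or erythroid marker reached the minimum. Of the sex-linked genes Xist, the RNA of the inactive X chromosome, had 4730 and 2849 counts, a log2 ratio of -0.67 that was -0.073 with the length trend removed.

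Macrophage identity genes differed little. None of the 22 measured members passed the size rule, and the median log2 ratio was 0.17 (-0.16 to 0.26). Mpeg1, the most abundant, had a log2 ratio of 0.20, Fcgr1, the high-affinity IgG receptor, 0.68 and Adgre1, which encodes F4/80, -0.43. The median was at percentile 98.6 of the expression-matched lists and at percentile 80.3 when length was matched too, and it was -0.012 with the length trend removed. Alternative activation genes had a median of -0.00051 over 13 members, at percentile 50.4, with Fn1 the 1 member past the size rule.

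Lysosomal, phagocytic and autophagy genes were slightly higher, with a median log2 ratio of 0.23 (0.12 to 0.31) and 27 of 35 members above 0. Fcgr4, an activating IgG receptor, was 2.53-fold higher, and Ctsh, a lysosomal protease, had a log2 ratio of 0.53. The median was at percentile 99.99 with expression matched and 100 with length matched too. Oxidative phosphorylation genes had a median of 0.21 (0.10 to 0.26) with none of 27 past the size rule, at percentile 100 with expression matched and 80.95 with length matched too. With the trend of the ratio with gene length removed, their median was -0.0099.

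Proliferation genes were slightly lower. The G1/S and DNA replication list had a median log2 ratio of -0.21 (-0.29 to -0.07) over 24 genes and the G2/M list -0.14 (-0.25 to -0.03) over 25, with no member of either past the size rule. Mki67, a proliferation marker, had a log2 ratio of -0.49, Cenpf -0.48 and Ccne1 -0.43. Mki67 and Cenpf have long transcripts and were at -0.082 and -0.047 with the length trend removed, while the medians of the G1/S and G2/M lists were then -0.24 and -0.12. The medians were at percentiles 0.04 and 2.12 with expression matched and 0.01 and 0.26 with length matched too. Glycolysis and hypoxia response genes had a median of -0.17 (-0.26 to 0.00) over 26 members, at percentile 0.37 with expression matched and 0.00 with length matched too, with the oxygen-responsive genes Egln3 and Ankrd37 2.87-fold and 2.35-fold lower.

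TGF-beta and BMP signalling genes had a median of -0.23 (-0.34 to 0.00) over 28 members, with Tgfb2 3.58-fold and Bmpr1a 2.03-fold lower. The list was at percentile 0.03 with expression matched and 0.84 with length matched too. Its median was -0.077 with the length trend removed, where Bmpr1a was at -0.83, and -0.12 with at least 100 counts. The microRNA machinery list had a median of -0.33 (-0.42 to 0.10), at percentile 0.03 with expression matched and 4.97 with length matched too, and its median was -0.036 with the length trend removed. Ago3 and Ago2, which encode Argonaute proteins that hold microRNAs, were 2.69-fold and 2.37-fold lower and had log2 ratios of -1.12 and -0.92 with the trend removed. Negative regulators of PI3K, AKT and mTOR had a median of -0.16, at percentile 2.52 with expression matched and 27.6 with length matched too, and 0.036 with the trend removed. Among them Pik3ip1 was 3.24-fold higher and Foxo3 2.01-fold lower. Immediate early and stress genes had a median of -0.066, at percentile 18.6 with expression matched and 0.59 with length matched too, but 0.066 with the trend removed and 0.094 with at least 100 counts. Fos was 2.16-fold lower.

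The LXR and lipid efflux list had a median of -0.15 (-0.44 to 0.17), with 7 of 21 members above 0. It was at percentile 2.03 with expression matched and 1.67 with length matched too, and its median was -0.057 with the length trend removed. Abca1, a cholesterol exporter, had a log2 ratio of -0.98 (-1.06 to -0.89), or -0.56 with the trend removed. Abcg1, of the same list, went the other way, at 0.52 (0.43 to 0.60), or 0.73 with the trend removed. Cholesterol synthesis and fatty acid genes had medians of 0.080 and -0.010, at percentiles 88.9 and 45.6 with expression matched and 88.6 and 16.8 with length matched too, and Cd36, a fatty acid and scavenger receptor, had a log2 ratio of -0.91. Toll-like receptor signalling genes had a median of -0.093 (-0.015 with the trend removed), at percentile 4.90 with expression matched and 8.53 with length matched too. The Bcl-2 family had a median of 0.070, at percentiles 75.7 and 59.4.

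**Figure D3:**
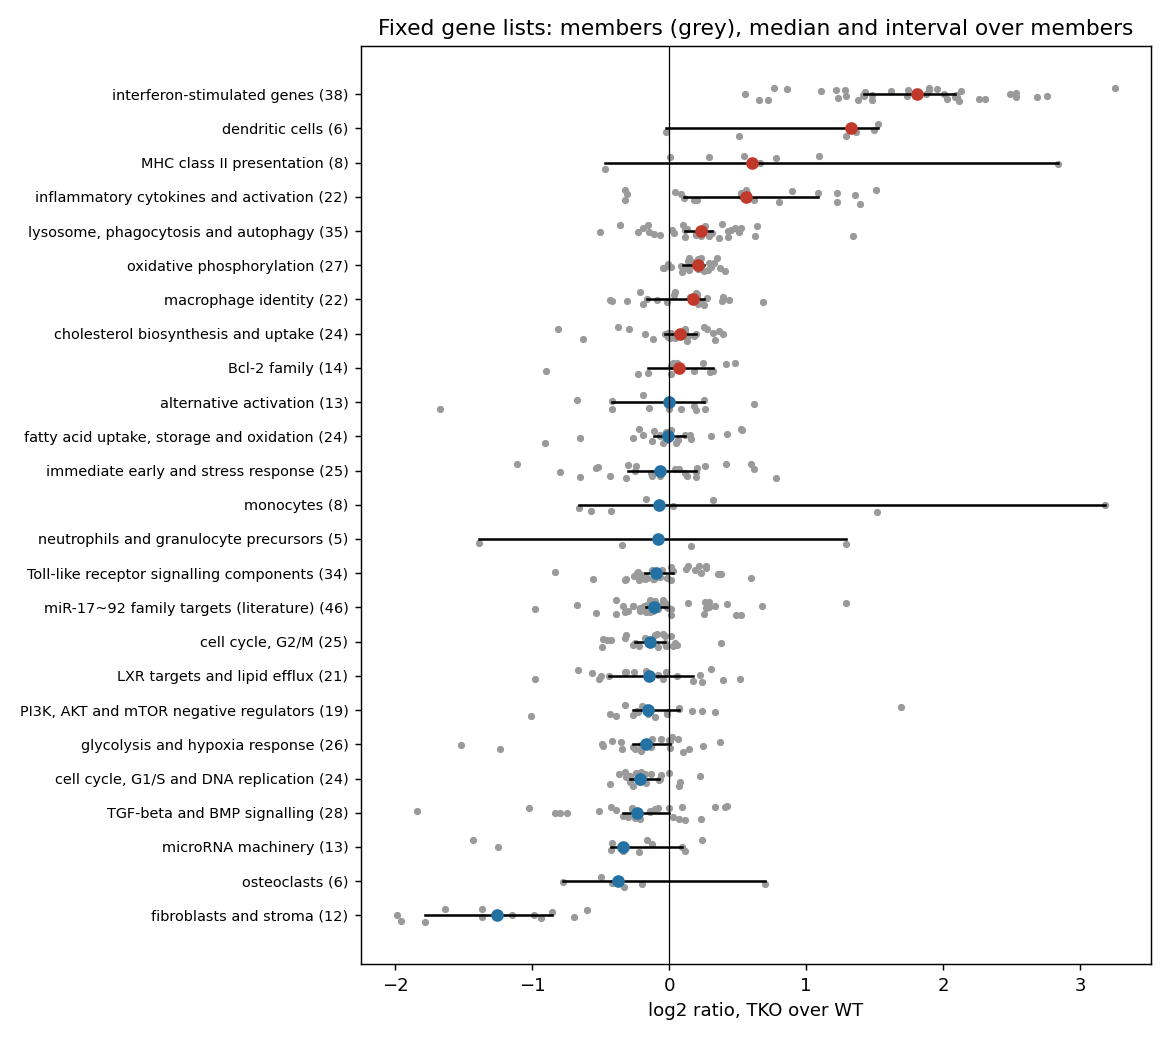
Log2 ratio of TKO over WT (x axis) for the members of each fixed list (y axis) with at least 3 measured members, given in brackets, where grey points are genes, coloured points are medians and bars are 95% order-statistic intervals over members. The interferon-stimulated list has the highest median, 1.81, and the fibroblast and stroma list the lowest, -1.25.

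Published targets of the miR-17~92 family were not higher as a group. Of 46 measured targets, 1 was higher and none lower by the size rule, with a median log2 ratio of -0.11 (-0.17 to -0.02), at percentile 1.64 with expression matched and 50.9 with length matched too, and their median was 0.024 with the length trend removed. The higher target was Socs1, an inhibitor of cytokine signalling, with 12 and 28 counts (log2 ratio 1.29, 0.27 to 2.40). Abca1 had -0.98, Atg16l1, an autophagy gene, 0.68 (0.46 to 0.90) and Egr2, a transcription factor, -0.67 (-1.16 to -0.20). Bcl2l11, which encodes the death-promoting protein BIM, had a log2 ratio of 0.013 (-0.092 to 0.12). Cdkn1a, a cell cycle inhibitor, had 0.49 (0.40 to 0.58), Tgfbr2 0.42, E2f1 -0.099 and Stat3 -0.21. Sirpa, a macrophage receptor, was the most abundant target and had -0.12.

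Seed sites for the microRNAs of these clusters were searched for in the annotated 3' UTRs of 11051 genes. The 1641 genes with a site of the miR-17 family, which includes miR-20 and miR-93, had a median log2 ratio of -0.064 (-0.086 to -0.044), against 0.012 for genes without one. The medians were -0.093 for 1028 genes with a miR-18 site, -0.074 for 1476 with a miR-19 site and -0.085 for 836 with a miR-25/92/363 site. All 4 sets were at percentile 0 of random lists matched on expression. With 3' UTR length matched too, the miR-17 set lay at percentile 99.1, on the other side of the lists, and the miR-18, miR-19 and miR-25 sets at 22.9, 68.1 and 35.5. The miR-17 site ranked at percentile 87.2 among 15603 heptamers, the miR-18 site at 31.4, the miR-19 site at 71.6 and the miR-25 site at 49.2, so each lay within the central 95%. The median of the miR-17 set was -0.064 against -0.083 for lists matched on 3' UTR length, so its side depended on the matching. The set was on the low side where 3' UTR length was not matched and on the high side where it was. With 3' UTR length matched, its 501 genes with an 8mer were at percentile 100. The 934 genes with sites of this family alone were at 99.95. With the trend with gene length removed, the median of genes with a site minus that of genes without was 0.021 for miR-17, -0.011 for miR-18, 0.011 for miR-19 and 0.021 for miR-25.

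Transcript length went with the ratio across all genes. The shortest length decile (107 to 1178 bases) had a median log2 ratio of 0.22 and the longest (6096 to 83437 bases) -0.32, and Spearman's rho between length and log2 ratio was -0.45 across 11525 genes, which are not independent replicates. Calls by the size rule followed length too, with 48 genes higher and 10 lower in the shortest decile and 4 higher and 51 lower in the longest. With the length trend removed, 270 genes were higher and 240 lower in TKO. Genes with a miR-17 site had a median 3' UTR of 2519 bases against 1040 without one.

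**Figure D4:**
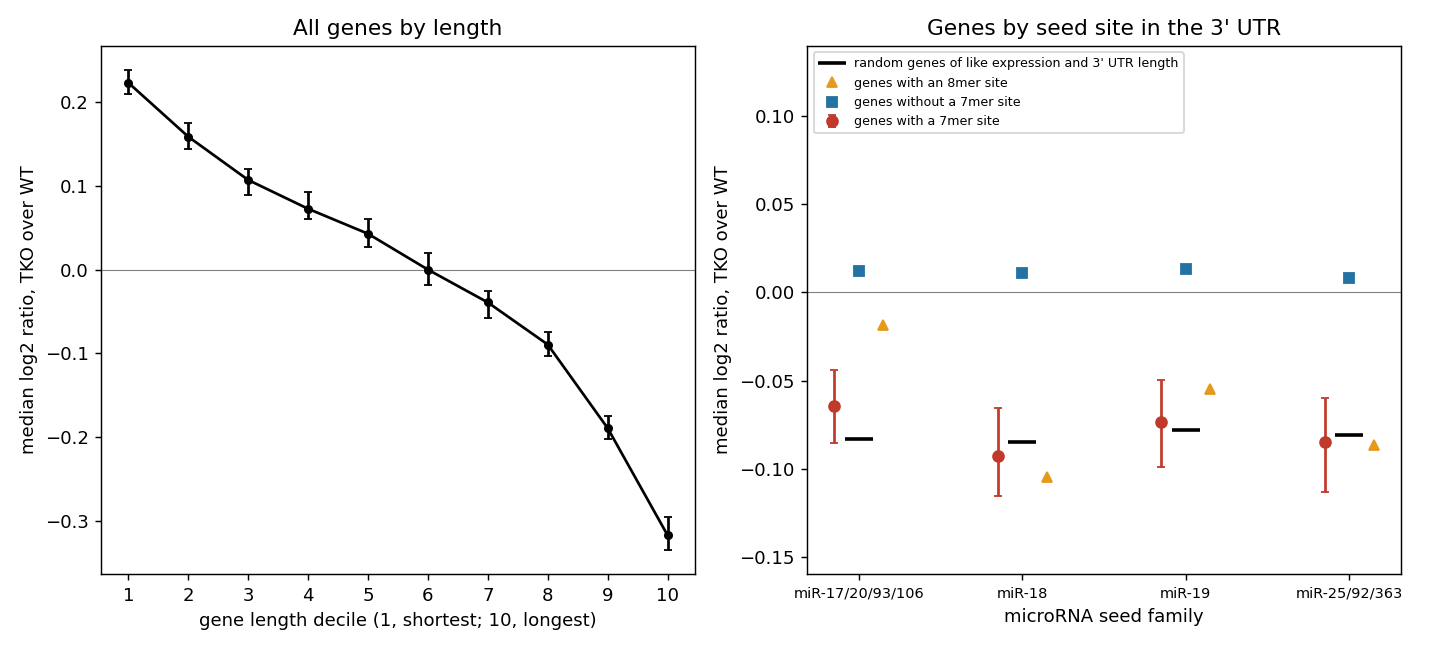
Left, median log2 ratio of TKO over WT (y axis) by gene length decile (x axis) with 95% order-statistic intervals over genes, from 0.22 to -0.32. Right, median log2 ratio (y axis) by microRNA seed family (x axis) for genes with a 7mer site (95% intervals over genes), with an 8mer site, without a 7mer site and for random genes of like expression and 3' UTR length, where the 8mer genes of the miR-17 family are at -0.019 and its 7mer genes at -0.064.

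Gene Ontology terms in the deposited table had MHC, interferon and matrix terms at the ends of their range. Of 1038 terms, 59 had a median in the highest 2.5% and 90 in the lowest 2.5% of random lists matched on expression and length. Terms of independent genes would put 26 on each side. Genes of a term can vary together and terms share genes, so 59 and 90 are no measure of an excess over chance. Regulation of T cell tolerance induction had 10 of 11 genes higher and a median log2 ratio of 5.55, with H2-L, H2-Q10 and H2-Q2 among them. In the response to interferon-beta, 17 of 24 genes were higher and the median log2 ratio was 1.64, and in the response to interferon-alpha 6 of 10 were higher (median 1.89). Proteinaceous extracellular matrix had 15 of 42 genes lower and a median of -0.52, and chondrocyte differentiation 5 of 14 lower and a median of -0.59.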

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

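The tests with the length trend removed, without the MHC region and on ranks after removing the 3' UTR trend were chosen only after the results were seen. Of 278 values under alternative settings, 248 kept their direction and their side of the limits, or stayed within their interval or 1.5 times the count. Library totals and DESeq2 factors gave 34 each of the 248, and leaving out the MHC region 26. These settings shift all ratios slightly or leave most lists unchanged, so the tally is no measure of robustness. Medians that changed sign within their interval were also counted among the 248. With 2 libraries, library totals and DESeq2 factors move every log2 ratio by the same amount, so they are no check of percentiles or of gaps between gene sets; they gave 262 and 271 higher and 292 and 276 lower genes. No paired analysis was possible because each genotype had 1 library. Pseudocounts of 0.1 and 5 were not run because counts were deposited, and the class II list without H2- genes had too few members. Genes higher and lower in TKO numbered 591 and 636 at 1.5-fold, 76 and 26 at 4-fold, and 164 and 95 with at least 100 counts, as wider or narrower limits must give. The lower genes numbered 122 with FPKM and 175 with a wider counting interval. In the authors' deposited table the stricter threshold left 74 higher and 33 lower. Mir17hg had a log2 ratio of 1.03 with FPKM plus 1, which shrinks low values. With gene length matched, percentiles were 50.89 for published miR-17~92 targets, 80.3 for macrophage identity, 80.95 for oxidative phosphorylation, 4.97 for microRNA machinery and 0.59 for immediate early genes. With the length trend removed, the medians of published targets and oxidative phosphorylation were 0.024 and -0.0099, and those of macrophage identity, PI3K regulators, immediate early genes, monocytes and alternative activation also changed sign, to -0.012, 0.036, 0.066, 0.057 and 0.014. The gap between genes with and without a site was then 0.021 for miR-17, -0.011 for miR-18, 0.011 for miR-19 and 0.021 for miR-25. For miR-17 the gap was -0.031 with 8mers, -0.052 with the shortest 3' UTR and -0.049 with sites of this family alone. With 3' UTR length matched, the percentiles were 99.12 for miR-17, 22.86 for miR-18, 68.06 for miR-19 and 35.47 for miR-25. The miR-17 8mer ranked at 99.6 among 8mers after the 3' UTR trend was removed, against 87.2 for the heptamer. Where the alternative's own construction does not show it, the cause was not tested. Depth limits genes of few counts, such as Mir17hg, whose 5.49-fold difference had an interval from 2.55 to 13.5.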

Other observations

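The tests of explanations, the count of genes near absent from 1 library and the ranks of sites after the 3' UTR trend was removed were chosen only after the results were seen.

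Genes present in 1 library and near absent from the other were not limited to the MHC. With at most 3 counts in 1 library and at least 30 in the other, 13 genes were higher in TKO, 6 of them in the MHC region or named H2-, and 7 were lower, none of which lay there.

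Seed-site results for the miR-17 family depended on the measure. Its 1641 genes were at percentile 0 of lists matched on expression and at 99.1 with 3' UTR length matched too, and its heptamer ranked at 87.2. The 501 genes with an 8mer were at percentile 100 and the 934 genes with sites of this family alone at 99.95 of lists matched on 3' UTR length. After the 3' UTR trend was removed the heptamer ranked at 90.0 and the 8mer at 99.6, with 40 of 11173 8mers as high. The 8mer rank was added after the heptamer rank was seen. The other 3 families, at percentile 0 with expression matched, stayed within the central 95% in each of the other measures. For miR-18, miR-19 and miR-25 the 8mer sets were at 46.1, 93.4 and 30.7, the sets of 1 family alone at 23.5, 84.0 and 15.4, the heptamers after trend removal at 32.3, 69.2 and 67.6 and the 8mers at 78.9, 69.0 and 55.2. These are 7 measures on 1 pair of libraries and do not decide whether targets of the miR-17 family differed.

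MHC region transcripts were higher in TKO, with H2-L at 22 and 7629 counts. A shift of reads between near-identical class I genes at an equal total was argued against by the summed counts, 1.72-fold higher (1.70 to 1.75). Interferon induction of the size seen in the interferon list was argued against as the cause for every class I gene, since 8 of 20 had intervals wholly above the list's highest log2 ratio of 3.25; it stays open for the other 12, and together with shared reads for all. A different MHC haplotype in the TKO line remains a candidate explanation, as C57BL/6 mice carry the b haplotype, in which the promoter of the class II gene Ea is deleted, and H2-Ea-ps had 0 and 118 counts. The result expected if this were the cause, a share above that of any other window, was not met. In the 4.5 Mb window 11.9% of 126 genes passed a log2 ratio of 2 (95% binomial interval 6.82 to 18.9). H2-L, H2-T9, H2-Q8 and H2-Q9 have no position in the annotation and were not counted. The share was the fifth highest of 200 windows and below the 25% of the highest (5 of 20 genes, 8.66 to 49.1), but the intervals overlap. All 5 genes of the highest window were Ifit genes, which belong to the interferon pattern, so the rank by share cannot decide the question. By number, the MHC window held 15 of the 94 genes past this ratio, among 11452 genes with a position. With 1 line per genotype a difference in strain and the genotype cannot be told apart.

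Interferon-stimulated genes were higher in TKO, which could follow from the genotype or from other differences between the cultures. The trend with gene length was argued against as the cause, since the median log2 ratio without it was 1.81 (1.43 to 1.99). Residence in the chromosome 17 segment was argued against too, since 38 of 38 measured members lay outside it. That follows from the annotation and the choice of list, not from the expression values. It does not bear on effects of the segment on genes elsewhere. More dendritic cells in the TKO library cannot be told apart from other causes, because the 6 measured markers had a median of 1.33 (-0.02 to 1.53), an interval that includes 0, and macrophages also express Itgax and Irf8. A difference in genetic background that acts on other chromosomes, and loss of the microRNAs itself, were not tested and stay open.

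Fibroblast and collagen transcripts were lower in TKO. The trend with gene length was argued against as the whole cause, since the median log2 ratio without it was -1.15 (-1.46 to -0.90). A larger share of stromal cells in the WT library may contribute, since all 12 measured markers had intervals wholly below 0, but their log2 ratios ran from -1.99 to -0.60 and did not share 1 ratio within counting error, and Col1a1, the most abundant, had 2871 and 693 counts, so this cannot be told apart from other causes. RNA from L929 fibroblasts in the medium was not tested, and neither was an effect of the genotype on matrix genes.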
